A study of Arabidopsis thaliana with 38 samples.

How the data were processed

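RNA was measured on 38 one-colour arrays of 11 groups, each a cell type or the whole embryo at 1 of 3 times after hand pollination. Per the labels, nuclei were isolated with INTACT, a two-component tagging system, and 1 isolation protocol is given for all groups. Nuclear RNA was extracted with TRIzol, amplified as cDNA with a whole-transcriptome kit for small amounts and labelled with biotin. Per the series design, the replicates of a group were pooled biological replicates, 3 or 4 per group, so that the p-values measure the spread between such pools.

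The deposited intensity values are on a linear scale and were made by the authors with RMA, per the submitters' processing notes. RMA corrects background, quantile-normalizes between arrays and summarises the probes of a probe set; its version and the probe set definition are not given in the sources used here. The deposited table held 1 value per locus and array for 27826 loci, and 0 of its columns belonged to no sample. The deposited arrays were not equal in distribution, with upper quartiles from 3.28 to 3.77 and interquartile ranges from 1.03 to 2.1 on the log2 scale. RMA between arrays of unlike cell types assumes like distributions, and differences in the overall level of RNA between nuclei are lost in it. No detection calls were used here, so dim genes near background are compressed towards a log2 change of 0. The number of arrays per group limits the precision of each value.

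Values were taken to log2 without an added constant. Groups were compared with limma (version 3.58.1, R 4.3.3), with all 38 arrays in 1 fit of 11 group means, no covariate, and eBayes with 1 prior variance for all genes. The fit had 27 residual degrees of freedom and a prior of 6.79, with a typical SD of 0.516. The design gave 15 comparisons of 2 groups, 3 tests of whether a cell type's difference from the whole embryo changed between 81 h and 100 h, and 3 counts of genes called the same way at both stages. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. No pair of arrays was a duplicate: the highest correlation of any pair was 0.896 (EMB_EG 1 and 3), with a mean absolute log2 difference of 0.47.

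Lists of genes were fixed from textbook knowledge: vascular (21 genes), ground tissue (8), suspensor (8), root meristem (19), protoderm (11), shoot apex and cotyledon (15), endosperm (13), seed coat (16), G2 and M phase (19), S phase (17), auxin response (44), auxin transport and synthesis (15), cytokinin (20), seed maturation (17), photosynthesis (23), stress response (12), and DNA methylation and Polycomb (23). They held 301 entries for 289 genes, all on the array. Each list was tested in each comparison with limma's camera at a preset correlation of 0.01, adjusted over 255 tests, and again with the correlation estimated per list and with fry. These lists, the tests with limma, camera and fry, the alternatives to them listed below and the rule for naming genes were chosen before the data were examined. Tests chosen afterwards are named below.

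By that rule, each comparison names the 6 largest rises and 6 largest falls among called genes with a symbol whose arrays do not overlap. It also names up to 6 genes of the list that belongs to the cell type and up to 3 of any other list that passed, by smallest adjusted p, the 2 genes of highest mean from the endosperm and seed coat lists, and the 4 genes of smallest adjusted p for each stage difference. Not every gene so chosen is printed, and a few results are not reported here. Locus identifiers were matched to the TAIR10.1 gene table for 27241 loci, of which 10560 have a symbol; symbols are given with their locus at first mention.

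The alternatives were quantile normalization, centring each array on its median, a filter on genes below the 25th percentile of mean intensity, array weights, an intensity trend in the prior, an added 2-fold threshold, only the arrays of the groups compared, the replicate number as a block, and leaving out each array in turn. Named genes were rerun with all of these but the filter and the threshold. Other splits of the same arrays were refitted, at most 100 per result, and permutation tests used 100000 resamples. Code was tested on simulated data of 27826 genes: in VSC_EG against EMB_EG 84 of 100 genes with a 4-fold change and 12 of 100 with a 2-fold change were recovered with 4 false calls, and in ILT_16C against EMB_16C 56 and 2 with 2 false calls. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.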

Results

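RNA from nuclei of Arabidopsis thaliana embryos was measured on 38 one-colour microarrays that report 27826 loci. The nuclei were isolated with INTACT, in which a tagged nuclear envelope protein driven by a promoter of the chosen cell type allows those nuclei to be captured on beads. Flowers were pollinated by hand, and embryos were taken 72 h (16-cell stage), 81 h (the stage labelled EG) and 100 h (the stage labelled LG) later. At 72 h the groups were the inner lower tier (ILT_16C, 3 arrays) and the whole embryo (EMB_16C, 3). At 81 h they were vascular cells (VSC_EG, 4), ground tissue cells (GSC_EG, 4), the suspensor (SUS_EG, 3), the filament that joins the embryo to the mother plant, and the whole embryo (EMB_EG, 4). At 100 h they were vascular cells (VSC_LG, 4), ground tissue cells (GSC_LG, 3), the suspensor (SUS_LG, 3), the group labelled QC (QC_LG, 3) and the whole embryo (EMB_LG, 4). The design compares nuclei of cell types with whole-embryo nuclei, with each other and between stages.

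Intensities were compared on the log2 scale. The array medians lay between 2.47 and 2.71, while the interquartile range of an array ran from 1.03 (QC_LG 2) to 2.1 (ILT_16C 1). The suspensor (2.2 to 2.78) and root meristem lists (2.19 to 2.74) averaged near these medians in every group. Uncalled genes there say little about cell identity. Arrays of one group correlated with a median r of 0.789 across genes and arrays of different groups with 0.738; genes are not independent replicates here. QC_LG 2 had the lowest mean r with its own group, 0.635. Changes are log2 differences with their standard errors (SE) from limma, and the p-values given for genes are Benjamini-Hochberg adjusted over all 27826 loci. Genes named as the largest rises and falls of a comparison were taken from those whose arrays did not overlap between the groups, which chance alone gives for 10% of genes with 3 against 3 arrays, 5.71% with 4 against 3 and 2.86% with 4 against 4. Genes named from a list can overlap, as LOG4 (AT3G53450) did in VSC_LG and EMB_LG. Comparisons with the whole embryo of one stage share those whole-embryo arrays.

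**Figure D1:**
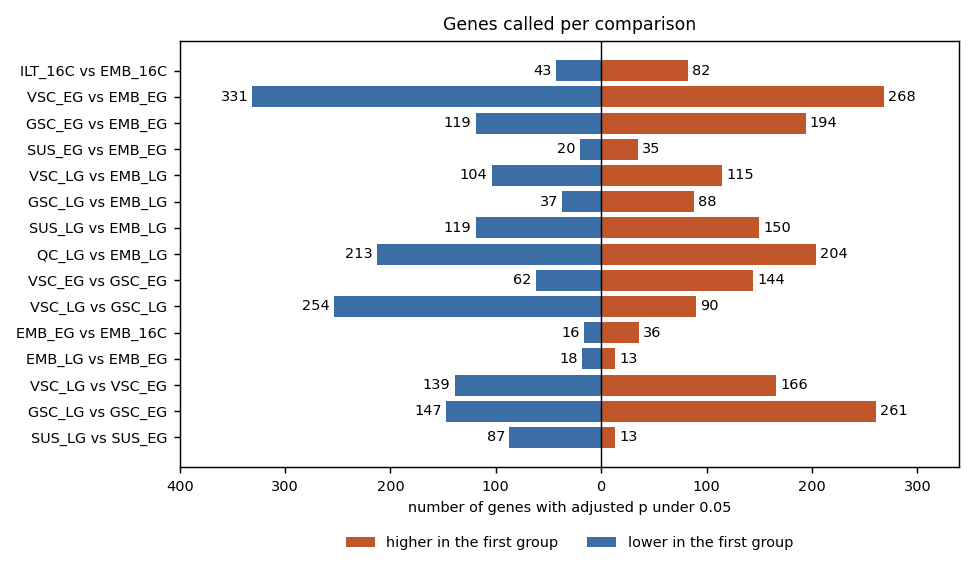
Number of genes called higher (right) and lower (left) in the first group of each comparison, at an adjusted p under 0.05 in limma. The counts ran from 31 for EMB_LG against EMB_EG to 599 for VSC_EG against EMB_EG.

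In the inner lower tier at the 16-cell stage, stress response genes were higher as a list and genes of the G2 and M phase lower (adjusted p = 0.056 for the latter with an estimated correlation) than in the whole embryo (3 arrays each). HSP17.6II (AT5G12020), a small heat shock protein, rose by 3.42 (SE 0.743, adjusted p = 0.0311), GRP9 (AT2G05440), a glycine-rich protein, by 3.35 and TCH4 (AT5G57560), a cell wall enzyme induced by touch, by 3.27. LYK5 (AT2G33580), a receptor of chitin, and HRGP1 (AT3G54590) rose by 3.00 and 2.95. WOX2 (AT5G59340), a homeobox gene of the upper embryo, fell by 2.46 (SE 0.42, adjusted p = 0.00611), from 4.08 ± 0.811 (SD, n = 3) in the whole embryo to 1.62 ± 0.25. CYP78A5 (AT1G13710), which promotes organ growth, fell by 2.79, and SAP (AT5G35770), a floral regulator, by 2.32. In all, 82 genes were higher and 43 lower, and 0 of 13 named calls held in every rerun.

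Of the 12 stress response genes, 1 rose and 11 did not pass, against 6 that rose when adjusted over the list alone; their mean was 1.29 (camera adjusted p = 5.7e-07). Of 19 genes of the G2 and M phase, 1 fell, CYCB2;4 (AT1G76310) by 1.80, and 18 did not pass, with 4 falling when adjusted over the list alone; the list mean was -0.82 (camera adjusted p = 1.18e-06, but adjusted p = 0.056 with an estimated correlation). Lower as lists, with 0 members called in each, were S phase (mean -0.51; CDC45 [AT3G25100] -1.67), DNA methylation and Polycomb (-0.44; VIM1 [AT1G57820] -2.40), photosynthesis (-0.48; LHCA4 [AT3G47470] -0.82), vascular (-0.46; ATHB-15 [AT1G52150] -1.09, adjusted p = 0.0591) and root meristem (-0.47; BBM [AT5G17430] -2.15). Their camera adjusted p were 0.0045, 0.00508, 0.00133, 0.0045 and 0.0114, and with an estimated correlation each was lost (adjusted p = 0.33, 0.357, 0.15, 0.116 and 0.129). Adjusted over the list alone, 3 vascular, 2 root meristem and 1 DNA methylation and Polycomb gene fell. The ground tissue list had a mean of 0.02 and 0 of 8 members called. The seed coat list, markers of maternal tissue, was higher (mean 0.35, camera adjusted p = 0.0313; adjusted p = 0.538 with an estimated correlation), a call that was also lost with array weights, with TT8 (AT4G09820) at 1.27 (adjusted p = 0.321). It rested on single arrays: without ILT_16C 1 its mean was -0.05 and without EMB_16C 2 0.07. It was 0.53, 0.56 and 0.53 without ILT_16C 2, ILT_16C 3 or EMB_16C 1, and the array spread as a covariate also ended the call (adjusted p = 0.0849). The root meristem call ended without ILT_16C 1 (mean -0.31) or EMB_16C 1 (adjusted p = 0.0811), and the DNA methylation and Polycomb call without ILT_16C 2 or EMB_16C 1 (adjusted p = 0.128 and 0.0796). The count of 125 genes became 37 with array weights, 14 with only the arrays compared in the fit and 193 with the array spread as a covariate. Leaving out ILT_16C 2 or 3 gave 69 or 71 genes, and leaving out EMB_16C 1, 2 or 3 gave 65, 51 or 72.

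Vascular nuclei at 81 h had 268 genes higher and 331 lower than whole-embryo nuclei (4 arrays each). WRKY40 (AT1G80840), a transcription factor of the defence response, rose by 3.39 (SE 0.609, adjusted p = 0.00242), from 3.73 ± 0.826 to 7.12 ± 0.744 (SD, n = 4). JAZ7 (AT2G34600), a repressor of jasmonate signalling, rose by 2.64 and the F-box gene FBS3 (AT4G05010) by 3.45. The symbol PBP1 belonged to a pair of loci that moved apart: AT5G54490, a calcium-binding protein, rose by 2.80, and AT3G16420, a lectin that binds the glucosidase PYK10 (AT3G09260), fell by 3.29. PYK10 itself fell by 4.30 (SE 0.543, adjusted p = 9.16e-05), GRP9 by 4.32, DOT1 (AT2G36120) by 4.08 and the ribosomal protein gene RPS5A (AT3G11940) by 3.18.

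None of the 21 vascular list genes passed, 0 also when adjusted over the list alone; MP (AT1G19850), the auxin response factor of vascular initiation, stood at -1.43 (adjusted p = 0.178) and TMO5 (AT3G25710) at 0.90 (0.301), and the list mean was 0.05. Of 23 photosynthesis genes 5 fell and 18 did not pass, with 14 falling when adjusted over the list alone. PSBO1 (AT5G66570), of the oxygen-evolving complex, fell by 1.57, LHCB4.1 (AT5G01530) by 1.61 and PSBP-1 (AT1G06680) by 1.28; the list mean was -0.96 (camera adjusted p = 1.21e-10). Of the 12 stress response genes 1 rose, WRKY40, and 4 did when adjusted over the list alone; JAZ1 (AT1G19180) stood at 1.23 and TCH4 at 1.73, with adjusted p = 0.107 and 0.136. The stress list mean was 1.03 (camera adjusted p = 0.000118, but adjusted p = 0.0868 with an estimated correlation). Of the highest markers of maternal seed coat and of endosperm, TT4 (AT5G13930) stood at -0.40 and IKU1 (AT2G35230) at 0.05. The seed coat list stood at -0.31 (camera adjusted p = 0.161), with 1 gene falling when adjusted over the list alone. Of the 15 named calls 9 held in every rerun, among them WRKY40, JAZ7, PYK10 and RPS5A. The 599 calls became 2010 with array weights, 279 with only these groups in the fit and 96 without VSC_EG 2 and 3, which correlated more with each other (r = 0.845) than any other pair of the group (at most 0.791). Without VSC_EG 1, 2, 3 or 4 the counts were 985, 219, 210 and 916, and without EMB_EG 1, 2 or 3 they were 230, 294 and 265.

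WRKY40 and HSP70 (AT3G12580) led the named rises in ground tissue nuclei at 81 h, where 194 genes were higher and 119 lower than in the whole embryo (4 arrays each). The chaperone HSP70 rose by 3.37 (SE 0.505, adjusted p = 0.000578), from 3.19 ± 0.649 to 6.56 ± 0.991 (SD, n = 4), the heat shock factor HSFA2 (AT2G26150) by 3.36, the coactivator of the heat response MBF1C (AT3G24500) by 3.23, HSP17.6II by 3.12 and WRKY40 by 3.47. LTP2 (AT2G38530), a lipid transfer protein, fell by 2.85, PYK10 by 2.51, the carbonic anhydrase CA2 (AT5G14740) by 2.25, the glycine-rich GRP-3 (AT2G05520) by 2.19, and the light-harvesting protein LHB1B1 (AT2G34430) by 2.14 (SE 0.448, adjusted p = 0.0129).

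Of the 12 stress response genes 6 rose and 6 did not pass, against 10 when adjusted over the list alone, with a mean of 2.11 (camera adjusted p = 2.57e-18). The photosynthesis list had a mean of -0.74 (camera adjusted p = 9.67e-08): 2 of 23 genes fell, PSBP-1 by 1.37 and LHCA4 by 1.20, and 7 did when adjusted over the list alone, while PSBO1 stood at -1.41 (adjusted p = 0.0544). None of the 8 ground tissue genes passed in either adjustment: SCR (AT3G54220), which specifies the endodermis, stood at -0.34 (adjusted p = 0.813) and JKD (AT5G03150), its zinc finger partner, at -0.39, with a list mean of -0.31. The 313 calls became 195 with quantile normalization, 973 with array weights and 141 with the array spread as a covariate. The count was 150, 201 or 147 without GSC_EG 1, 2 or 3, and 144, 186, 203 or 175 without EMB_EG 1, 2, 3 or 4.

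Suspensor nuclei at 81 h (3 arrays against 4) had 35 genes higher and 20 lower. HSP70 rose by 4.03 (SE 0.546, adjusted p = 0.00042), from 3.19 ± 0.649 (SD, n = 4) to 7.22 ± 0.406 (n = 3), the chaperone HSP90.1 (AT5G52640) by 3.29 and MBF1C by 3.28. The other leading rises were LCR72 (AT2G02140), a small cysteine-rich protein, at 3.82, AGP11 (AT3G01700), an arabinogalactan protein of pollen, at 3.32 and PGA4 (AT1G02790), a polygalacturonase of pollen, at 3.30. NAI2 (AT3G15950), which builds ER bodies, fell by 3.46, the extensin EXT4 (AT1G76930) by 2.95, the nitrate reductase NIA2 (AT1G37130) by 1.71, and the xylosidase BXL1 (AT5G49360) by 1.63. WOX8 (AT5G45980), a homeobox gene of the suspensor, stood at 1.11 (SE 0.41, adjusted p = 0.409) and WOX9 (AT2G33880) at 1.12 (adjusted p = 0.51), and 0 of the 8 suspensor genes passed, 0 also when adjusted over the list alone (list mean 0.26, camera adjusted p = 0.283).

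Of the 12 stress response genes 4 rose, HSFA2 by 2.94 among them, and 5 did when adjusted over the list alone (mean 1.73, camera adjusted p = 5.59e-13). The photosynthesis list was lower with 0 of 23 genes called in either adjustment (mean -0.36, camera adjusted p = 0.0064; adjusted p = 0.242 with an estimated correlation), and GLK2 (AT5G44190), a regulator of chloroplast development, stood at -1.16; without SUS_EG 1 or EMB_EG 3 the call ended (adjusted p = 0.08 and 0.0866). Beside the pollen genes named above, a list of 25 other pollen genes, chosen after the named genes were seen, had a mean of 0.72 (camera adjusted p = 6.49e-06; adjusted p = 0.117 with an estimated correlation). Of the named calls, HSP70 alone held in every rerun. The 55 calls became 156 with array weights. Without SUS_EG 2 or 3 there were 16 or 6, and without EMB_EG 1, 2 or 3 there were 30, 27 or 26.

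Vascular nuclei at 100 h had 115 genes higher and 104 lower than whole-embryo nuclei (4 arrays each). The peptide gene RALFL19 (AT2G33775) rose by 3.48 (SE 0.561, adjusted p = 0.00203), the chaperone HSP101 (AT1G74310) by 3.29, FLA11 (AT5G03170), a fasciclin-like protein of secondary cell walls, by 3.17, and MBF1C by 2.78. EXT4 fell by 3.60 (SE 0.563, adjusted p = 0.00159), GRP9 by 3.01, CA2 by 3.00 and the cell wall protein CWLP (AT3G22120) by 2.85. LOG4, which releases active cytokinin in the vascular domain, rose by 2.37 (SE 0.558, adjusted p = 0.0319), from 2.00 ± 1.23 to 4.37 ± 1.26 (SD, n = 4), and was 1 of 21 vascular genes called, also when adjusted over the list alone; MP stood at -1.30, and the list mean was -0.03.

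Of 23 photosynthesis genes 6 fell, PSAF (AT1G31330) by 1.93, RBCS1A (AT1G67090) by 1.52 and PSAE-1 (AT4G28750) by 2.22, and 18 did when adjusted over the list alone (mean -1.33, camera adjusted p = 2.71e-24). Stress response genes rose, 5 of 12 and 9 when adjusted over the list alone, with HSP70 at 2.61 and HSFA2 at 2.00 (mean 1.67, camera adjusted p = 6.59e-13). The protoderm list, of the outer layer, had a mean of -0.59 with 0 of 11 called and 1 when adjusted over the list alone (camera adjusted p = 0.00152; adjusted p = 0.129 with an estimated correlation), and ATML1 (AT4G21750) stood at -1.32 (adjusted p = 0.0947). The S phase list had a mean of -0.51 (camera adjusted p = 0.000704; adjusted p = 0.248 with an estimated correlation), with MCM6 (AT5G44635), a subunit of the replicative helicase, falling by 1.41 as the single call of 17 and 4 falling when adjusted over the list alone. The G2 and M phase list stood at -0.42 and the shoot apex and cotyledon list at -0.28, each with 0 called in either adjustment and with CDKB2;2 (AT1G20930) at -1.17 and CUC1 (AT3G15170) at -0.84. Camera adjusted p for this pair were 0.00442 and 0.0419, lost with an estimated correlation (adjusted p = 0.26 each); the shoot apex call was also lost without dim genes. Without EMB_LG 4 the S phase and G2 and M phase means were -0.28 and -0.26 and both calls ended, the latter also without EMB_LG 1 (adjusted p = 0.0502). The shoot apex call ended without EMB_LG 1, 3 or 4 or VSC_LG 1, 2 or 3 (adjusted p = 0.0614 to 0.139). Beside RALFL19, the 25 other pollen genes had a mean of 0.87 (camera adjusted p = 7.49e-09). Of the 19 named calls 10 held in every rerun, EXT4, CA2, RALFL19 and HSP101 among them but not LOG4. The 219 calls became 338 with quantile normalization and 386 with array weights. Without VSC_LG 2 or 3 there were 114 or 77, and without EMB_LG 1, 3 or 4 there were 137, 77 or 113.

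In ground tissue nuclei at 100 h (3 arrays against 4), 88 genes were higher and 37 lower. FIL (AT2G45190), a YABBY factor of the outer side of lateral organs, rose by 2.91 (SE 0.434, adjusted p = 0.00137), from 3.85 ± 0.63 (SD, n = 4) to 6.76 ± 0.521 (n = 3). The secondary wall cellulose synthases CESA4 (AT5G44030) and IRX1 (AT4G18780) rose by 2.77 and 2.54, the laccase LAC2 (AT2G29130) by 3.18 and FLA11 by 2.99. GRP9 fell by 4.26 (SE 0.687, adjusted p = 0.00228), EXT4 by 2.68 and CA2 by 2.61. SCR stood at 1.68 (SE 0.451, adjusted p = 0.0854), from 3.85 ± 0.797 (n = 4) to 5.53 ± 0.39 (n = 3), and JKD at 1.13 (0.244); 0 of 8 ground tissue genes passed, and 2 rose when adjusted over the list alone.

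Photosynthesis genes fell in 6 of 23 cases, LHCB2.2 (AT2G05070) by 2.43 and PSBO2 (AT3G50820) by 2.66, as did LHB1B1, outside the list, by 3.20. Adjusted over the list alone 17 fell, and the list mean was -1.38 (camera adjusted p = 7.75e-18). The stress response list had a mean of 1.33 (camera adjusted p = 3.4e-07), with 1 of 12 genes rising, HSFA2 by 2.26, and 8 when adjusted over the list alone. Lists of DNA methylation and Polycomb (mean 0.56, 22 of 23 genes above 0), G2 and M phase (0.51) and S phase (0.47) were higher with 0 genes called in each; 2 genes of the G2 and M phase rose when adjusted over the list alone, and 0 of the others. Their camera adjusted p were 6.78e-06, 0.0101 and 0.00981 and were lost with an estimated correlation (adjusted p = 0.127, 0.312 and 0.364), the S phase call also with quantile normalization (mean 0.31). VRN2 (AT4G16845) stood at 0.86 and KN (AT1G08560), the syntaxin of the cell plate, at 1.79. With the array spread as a covariate the DNA methylation and Polycomb mean was 0.18 and that of S phase 0.20, both no longer called. Without GSC_LG 2 they were 0.30 and 0.22, the latter not called. The S phase call also ended without EMB_LG 2 or 3 (means 0.28 and 0.31) and the G2 and M phase call without EMB_LG 2 (0.33). The array spread was wide in GSC_LG (interquartile range 1.51 to 2.06, against 1.24 to 1.42 in EMB_LG), and the 125 calls became 13 with that spread as a covariate, 79 with quantile normalization and 306 with array weights. Leaving out GSC_LG 1, 2 or 3 gave 53, 36 or 78, and leaving out EMB_LG 2 or 3 gave 63 or 54.

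Suspensor nuclei at 100 h (3 arrays against 4) had 150 genes higher and 119 lower. The calcium-dependent kinase CPK28 (AT5G66210) rose by 3.53 (SE 0.499, adjusted p = 0.000173), NPR3 (AT5G45110), a salicylic acid receptor, by 2.90, MYB73 (AT4G37260) by 3.10 and the RNA-binding PUM12 (AT5G56510) by 3.24. RBCS1B (AT5G38430), a small subunit of Rubisco, fell by 4.86 (SE 0.569, adjusted p = 1.67e-05), from 7.68 ± 0.583 (SD, n = 4) to 2.83 ± 1.54 (n = 3). VIM1, which maintains DNA methylation, fell by 3.03, EXT4 by 3.05 and the lectin PBP1 (AT3G16420) by 2.99. No suspensor gene passed in either adjustment (WOX8 0.63, adjusted p = 0.673; list mean -0.06, against a list median of 0.13).

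Of 23 photosynthesis genes 14 fell, PSAF by 2.58 and LHCB2.2 by 2.80, and 19 did when adjusted over the list alone (mean -1.70, camera adjusted p = 4.74e-30). Stress response genes had a mean of 1.25 (camera adjusted p = 8.96e-07), with JAZ1 rising by 2.09, ZAT12 (AT5G59820) by 2.29 and TCH4 by 2.56, 3 of 12 in all and 5 when adjusted over the list alone. All 16 seed coat genes lay above 0 (mean 0.90, camera adjusted p = 4.5e-08; adjusted p = 0.0984 with an estimated correlation): TT8 and TT2 (AT5G35550), regulators of tannin synthesis in the maternal seed coat, rose by 1.98 and 2.50, LDOX (AT4G22880) stood at 1.36, and 6 rose when adjusted over the list alone. Cell cycle lists were lower, with MAP65-3 (AT5G51600) falling by 1.55 and MCM6 by 1.33 as the single calls; G2 and M phase had a mean of -0.75 (camera adjusted p = 3.49e-06; 0.0631 as the adjusted p with an estimated correlation) and S phase of -0.55 (0.0011; adjusted p = 0.26 with an estimated correlation), with 1 and 2 falling when adjusted over the list alone. Lower with 0 called were the shoot apex and cotyledon list (mean -0.42; ANT [AT4G37750] -1.28; 1 fell when adjusted over the list alone) and the vascular list (-0.41; TMO5 -1.17; 1 rose, AT1G05577 at 1.56). Camera gave adjusted p = 0.00442 and 0.0178, lost with an estimated correlation (adjusted p = 0.116 and 0.19). The vascular call ended without SUS_LG 2 (mean -0.19), EMB_LG 1 or EMB_LG 4 (adjusted p = 0.0526 and 0.0895), and the S phase call without EMB_LG 4 (mean -0.32). The 269 calls became 156 with only these groups fitted. The 25 other pollen genes had a mean of 0.38 (camera adjusted p = 0.0247; adjusted p = 0.485 with an estimated correlation), not called without SUS_LG 1 (mean 0.22) or EMB_LG 4 (adjusted p = 0.0738). Without SUS_LG 2 or 3 there were 54 or 86 calls, and without EMB_LG 1, 3 or 4 there were 147, 136 or 158.

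Nuclei of the group labelled QC had 204 genes higher and 213 lower than whole-embryo nuclei at 100 h (3 arrays against 4). RBCS1B fell by 5.41 (SE 0.569, adjusted p = 1.23e-06), from 7.68 ± 0.583 (SD, n = 4) to 2.27 ± 0.865 (n = 3), GRP9 by 4.36, DOT1 by 3.67, PYK10 by 3.44, CWLP by 3.34 and the lectin PBP1 (AT3G16420) by 3.24. The root meristem gene WIP4 (AT3G20880), a zinc finger factor of root initiation, rose by 1.56 (SE 0.374, adjusted p = 0.0235), the single call of 19, also when adjusted over the list alone. WOX5 (AT3G11260), the homeobox gene of the quiescent centre, stood at 1.13 (SE 0.385, adjusted p = 0.153), from 2.50 ± 0.471 to 3.63 ± 0.593, and the list mean was 0.24 (camera adjusted p = 0.158). Genes known from pollen led the rises, ANX2 (AT5G28680), a receptor kinase of pollen tubes, by 3.39 and the proton pump HA8 (AT3G42640) by 3.41, with the peptide genes RALFL8 (AT1G61563) by 4.01 and RALFL19 by 3.24. The 25 other pollen genes had a mean of 1.27 with 5 rising (camera adjusted p = 2.39e-12), and of 0.76 without QC_LG 3.

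Among the 23 photosynthesis genes 14 fell, LHCA4 by 3.08 and RBCS1A by 2.10, and 20 did when adjusted over the list alone (mean -1.97, camera adjusted p = 2.35e-35). The stress response list had a mean of 0.84 (camera adjusted p = 0.00425; adjusted p = 0.212 with an estimated correlation), with JAZ1 rising by 2.03 as the single call of 12 and 5 rising when adjusted over the list alone. Cell cycle lists were lower by camera (adjusted p = 0.00185 and 0.0326), but adjusted p = 0.223 and 0.465 with an estimated correlation: G2 and M phase stood at -0.56 (HIK [AT1G18370] -1.72, 0 of 19 called, 4 falling when adjusted over the list alone) and S phase at -0.35 (MCM6 fell, with adjusted p = 0.0167, as the single call of 17, 2 when adjusted over the list alone). The protoderm list stood at -0.49 (PDF1 [AT2G42840] -1.73, adjusted p = 0.0644; 0 of 11 called, 1 falling when adjusted over the list alone; camera adjusted p = 0.0358; adjusted p = 0.317 with an estimated correlation). Array weights also ended the S phase and protoderm calls, and quantile normalization and leaving out dim genes the protoderm call. Without QC_LG 2 the protoderm and S phase means were -0.23 and -0.15 and both calls ended. The S phase call also ended without QC_LG 1 (adjusted p = 0.0611), EMB_LG 1 or EMB_LG 4 (means -0.22 and -0.12), with means of -0.55 and -0.54 without QC_LG 3 or EMB_LG 2. The protoderm call ended without EMB_LG 1 or 4 (adjusted p = 0.129 and 0.109) and the stress response call without QC_LG 3 (adjusted p = 0.0606). Of 17 named calls 5 held in every rerun, not WIP4. The 417 calls became 664 with quantile normalization and 43 with only these groups fitted. Without QC_LG 3 there were 149 and without EMB_LG 3 or 4 there were 253 or 233.

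**Figure D2:**
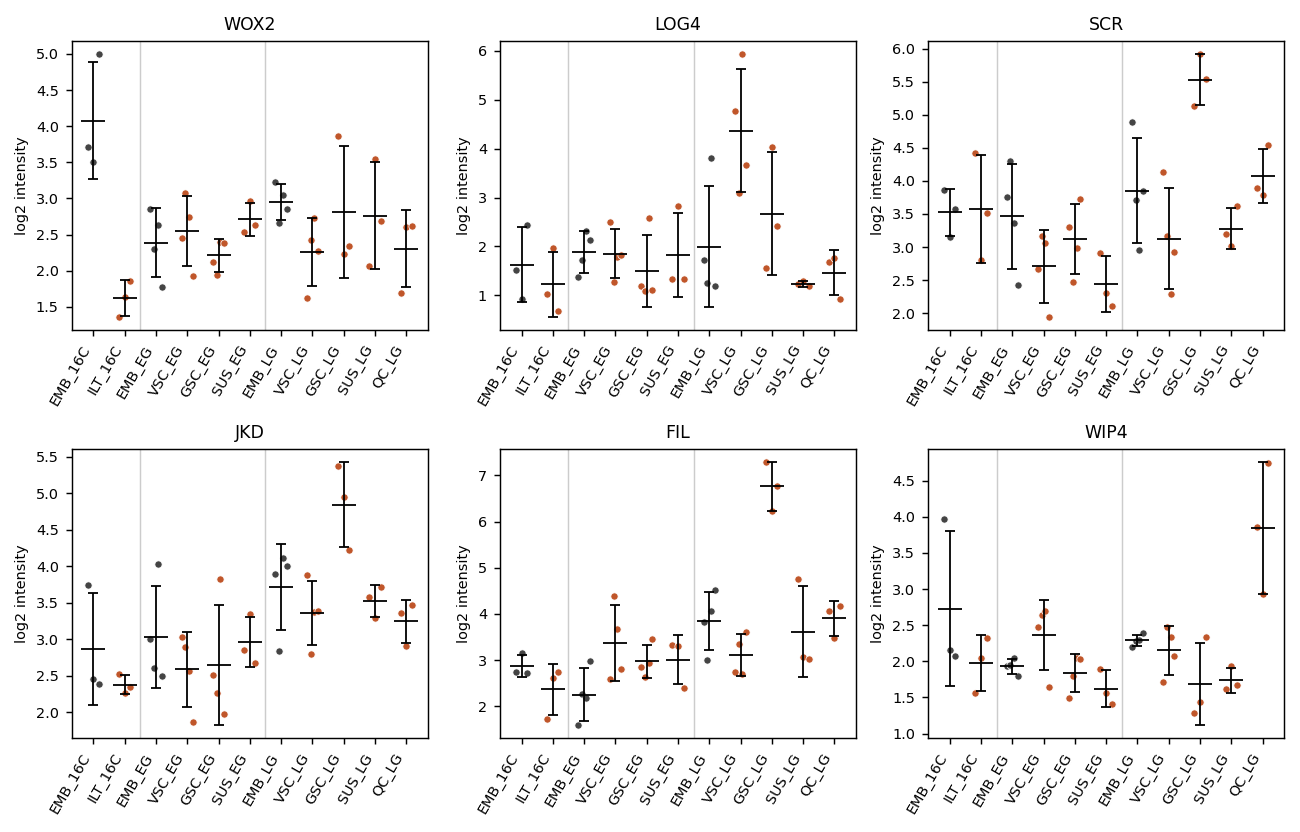
Log2 intensity of WOX2, LOG4, SCR, JKD, FIL and WIP4 on each of the 38 arrays, by group (points: arrays, whole embryo in grey; bars: mean ± SD; lines separate the stages). FIL lay at 6.76 ± 0.521 (n = 3) in GSC_LG and 3.10 ± 0.455 (n = 4) in VSC_LG.

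Between vascular and ground tissue nuclei at 81 h (4 arrays each), HSP70 differed most among the genes named. It was lower in vascular nuclei by 3.60 (SE 0.505, adjusted p = 0.000915), at 2.96 ± 0.199 against 6.56 ± 0.991 (SD, n = 4), and the chaperone Hsp70-15 (AT1G79920) had a log2 difference of -2.59. AGP22 (AT5G53250), an arabinogalactan protein, stood at -2.64, and the pectin methylesterase PME5 (AT5G47500) at -2.16, both called. Higher in vascular nuclei were MIR845a (AT4G23387) by 2.56, the heme oxygenase HO2 (AT2G26550) by 2.19 and ZPR4 (AT2G36307), a small inhibitor of class III homeodomain factors, by 1.97. In all 144 genes were higher and 62 lower. The stress response list was lower in vascular nuclei, with 2 of 12 called, HSP70 and HSFA2 (-2.61), 4 when adjusted over the list alone, and a mean of -1.08 (camera adjusted p = 2.28e-05; adjusted p = 0.0628 with an estimated correlation).

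No vascular or ground tissue gene passed, 0 also when adjusted over each list alone. REV (AT5G60690), a class III homeodomain gene, stood at -0.95 (adjusted p = 0.204), SHR (AT4G37650) at 0.79 and SCR at -0.41, and the list means were -0.12 and -0.02. The DNA methylation and Polycomb list stood at -0.30 with 0 of 23 called in either adjustment (EMF2 [AT5G51230] -0.93; camera adjusted p = 0.0404; adjusted p = 0.509 with an estimated correlation), a call also lost with quantile normalization, array weights or without dim genes, with the array spread as a covariate (mean -0.09), without GSC_EG 3 (-0.12), and without GSC_EG 4 or VSC_EG 1 (adjusted p = 0.0566 and 0.155). HSP70 alone of the 13 named calls held in every rerun. The 206 calls became 45 with quantile normalization, 110 without dim genes, 1019 with array weights, 5 with only these groups fitted, 68 with the array spread as a covariate and 6 without VSC_EG 2 and 3. Without VSC_EG 1, 2, 3 or 4 there were 566, 10, 38 and 720, and without GSC_EG 1, 2 or 3 there were 43, 135 and 48.

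At 100 h, vascular nuclei (4 arrays) and ground tissue nuclei (3) differed in the organ polarity gene FIL and the ground tissue gene SCR. FIL was lower in vascular nuclei by 3.66 (SE 0.434, adjusted p = 2.28e-05), at 3.10 ± 0.455 (SD, n = 4) against 6.76 ± 0.521 (n = 3). SCR had a log2 difference of -2.40 (SE 0.451, adjusted p = 0.00703), at 3.13 ± 0.77 against 5.53 ± 0.39, and was the 1 of 8 ground tissue genes called, against 3 when adjusted over the list alone; JKD stood at -1.49 (adjusted p = 0.0611). The receptor kinases ER (AT2G26330) and ERL2 (AT5G07180) fell by 2.67 and 2.63, and the transporter ABCG15 (AT3G21090) by 3.01. Higher in vascular nuclei were the pollen arabinogalactan gene AGP23 (AT3G57690) by 3.72 (SE 0.786, adjusted p = 0.0166), LCR72 by 3.24 and RALFL19 by 3.17, and the 25 other pollen genes had a mean of 1.15 with 2 rising (camera adjusted p = 1.5e-09). Of 21 vascular genes 0 passed; adjusted over the list alone, 1 rose and 6 fell, with MP at -2.03 (adjusted p = 0.0736), AHP6 (AT1G80100) at -2.08 and LOG4 at 1.69.

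Lists of the cell cycle were lower in vascular nuclei by camera (adjusted p = 1.79e-06 and 1.15e-07), but adjusted p = 0.0605 and 0.0631 with an estimated correlation. G2 and M phase had a mean of -0.93, with 3 of 19 falling (KN by 2.63, CDKB2;2 by 2.06) and 7 when adjusted over the list alone, and S phase of -0.98, with 2 of 17 falling (MCM7 [AT4G02060] by 1.76, MCM6 by 1.29) and 10 when adjusted over the list alone. VIM1 fell by 2.51 as the single call of 23 DNA methylation and Polycomb genes, 7 when adjusted over the list alone (mean -0.82, camera adjusted p = 4.33e-08; adjusted p = 0.0631 with an estimated correlation). The protoderm genes GSO1 (AT4G20140) and HDG12 (AT1G17920) fell by 1.82 and 1.93, 2 of 11 and 5 when adjusted over the list alone (mean -0.97, camera adjusted p = 2.5e-05; adjusted p = 0.0516 with an estimated correlation). The shoot apex and cotyledon list stood at -0.49, with FIL as the single call and 2 when adjusted over the list alone (camera adjusted p = 0.0182; adjusted p = 0.195 with an estimated correlation). The seed maturation list was higher by the test (mean 0.65, camera adjusted p = 0.0365; adjusted p = 0.363 with an estimated correlation), but its called members, the regulators LEC1 (AT1G21970) and ABI3 (AT3G24650), fell, LEC1 with adjusted p = 0.0289 and ABI3 by 1.62. SESA4 (AT4G27170), a seed storage albumin, stood at 2.96 (adjusted p = 0.0678), and 7 rose and 3 fell when adjusted over the list alone. The seed coat list was higher with 0 called in either adjustment (mean 0.51, TT4 0.79; camera adjusted p = 0.0266; adjusted p = 0.531 with an estimated correlation). With the array spread as a covariate the means were -0.40 for DNA methylation and Polycomb, -0.43 for protoderm, 0.38 for seed maturation and 0.97 for seed coat, and the protoderm and seed maturation calls ended. The seed maturation call ended without VSC_LG 3 (mean 0.37) or any GSC_LG array (adjusted p = 0.0518 to 0.0612), the seed coat call without VSC_LG 1 (mean 0.28) or GSC_LG 3 (adjusted p = 0.126) and the shoot apex call without GSC_LG 3 (adjusted p = 0.0816). The median of all genes was 0.11 as deposited and 0.0051 after centring, so that directions are relative to it. In all 90 genes were higher and 254 lower. The 344 calls became 144 with quantile normalization, 895 with array weights and 17 with the array spread as a covariate. Without VSC_LG 2 or 3 there were 120 or 132, and without GSC_LG 1, 2 or 3 there were 164, 25 or 118. FIL, ABCG15 and ER held in every rerun.

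From 72 h to 81 h in the whole embryo (3 and 4 arrays), 36 genes were higher and 16 lower at 81 h. GRP9 rose by 4.28 (SE 0.687, adjusted p = 0.0024), EXT4 by 3.89, PYK10 by 3.70, from 4.50 ± 1.15 (SD, n = 3) to 8.20 ± 0.467 (n = 4) and HRGP1 by 2.70. SAP fell by 2.65. The vascular list was lower, with AT5G02460 falling by 2.65 as the single call of 21 and 3 when adjusted over the list alone (mean -0.45, camera adjusted p = 0.00202; adjusted p = 0.0868 with an estimated correlation).

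The photosynthesis list was higher at 81 h, with 22 of 23 genes above 0 and 0 called in either adjustment (mean 0.60, camera adjusted p = 3.27e-06); LHCB2.2 stood at 1.15 and PSBO1 at 1.07. The seed coat list was higher too (mean 0.55, GL2 [AT1G79840] 1.21, TT4 0.81, 0 of 16 called, 2 rising when adjusted over the list alone; camera adjusted p = 0.000218; adjusted p = 0.272 with an estimated correlation). Lower with 0 called were G2 and M phase (mean -0.53; CYCB1;1 [AT4G37490] -1.12), S phase (-0.49; CDC45 -1.18), root meristem (-0.32; PLT1 [AT3G20840] -2.28) and DNA methylation and Polycomb (-0.29; AGO9 [AT5G21150] -1.39), with 1, 0, 2 and 0 falling when adjusted over the list alone. Camera gave adjusted p = 0.000134, 0.004, 0.0477 and 0.0404, each lost with an estimated correlation (adjusted p = 0.127, 0.317, 0.244 and 0.509); without dim genes the latter pair was also lost. The seed coat call ended without EMB_16C 2 (mean 0.27). The root meristem call ended without EMB_16C 1 or 2 or EMB_EG 1, 2 or 3 (adjusted p = 0.0541 to 0.218), with quantile normalization (adjusted p = 0.0546) and with the array spread as a covariate (0.0532). The DNA methylation and Polycomb call ended with array weights and without EMB_16C 1 or 2 or EMB_EG 1 or 4 (adjusted p = 0.0612 to 0.271 for the latter). GRP9 and PYK10 held in every rerun. The 52 calls became 79 without dim genes, 184 with array weights, 7 with only these groups fitted and 93 with the array spread as a covariate. Without EMB_16C 1 there were 23 and without EMB_EG 1 there were 18.

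From 81 h to 100 h in the whole embryo (4 arrays each), 13 genes were higher and 18 lower at 100 h. The receptor kinase ERL2 rose by 2.87 (SE 0.494, adjusted p = 0.00485), from 2.63 ± 0.185 to 5.49 ± 0.86 (SD, n = 4), the bZIP factor PAN (AT1G68640) by 2.61, ABCG15 by 1.90 and MCM6 by 1.64. CUC1, which sets the boundary between the cotyledons, rose by 1.55 (adjusted p = 0.0384). The glucosidase BGLU18 (AT1G52400) fell by 2.01 (SE 0.328, adjusted p = 0.0034) and the receptor kinase EMS1 (AT5G07280) by 1.82.

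The shoot apex and cotyledon list was higher, with CUC1 as the single call of 15 and 3 when adjusted over the list alone (mean 0.52, camera adjusted p = 0.000108); FIL stood at 1.60 and ANT at 1.28. The S phase list was higher (mean 0.64, camera adjusted p = 5.7e-06; adjusted p = 0.116 with an estimated correlation), with MCM6 as the single call of 17, 4 when adjusted over the list alone and PCNA2 (AT2G29570) at 1.64, as was G2 and M phase (mean 0.42, 0.00115; adjusted p = 0.199 with an estimated correlation), with 0 of 19 called, 1 when adjusted over the list alone and MAP65-3 at 1.24 (adjusted p = 0.0937). Also higher were the vascular (0.42; LHW [AT2G27230] 0.97), DNA methylation and Polycomb (0.34; AGO4 [AT2G27040] 1.07) and seed maturation lists (0.28; ABI3 1.36), with 0 called, and 0, 0 and 1 rising when adjusted over the list alone. Their camera adjusted p were 0.00239, 0.0236 and 0.0404, and with an estimated correlation adjusted p = 0.0921, 0.457 and 0.364; array weights also ended the DNA methylation call and quantile normalization the seed maturation call. The photosynthesis list was lower with 0 called in either adjustment (mean -0.45, PSBO1 -0.95; camera adjusted p = 9.4e-05; adjusted p = 0.0867 with an estimated correlation), and so was the seed coat list (mean -0.62, AHA10 [AT1G17260] -1.92, 0 of 16 called, 1 when adjusted over the list alone; camera adjusted p = 2.35e-05; adjusted p = 0.217 with an estimated correlation). Without EMB_LG 4 the S phase and G2 and M phase means were 0.41 and 0.26, and the latter call ended. The DNA methylation and Polycomb call ended without EMB_EG 4, EMB_LG 1 or EMB_LG 4 (adjusted p = 0.186 to 0.209). The seed maturation call ended with the array spread as a covariate (adjusted p = 0.127) and without any array (adjusted p = 0.058 to 0.156) but EMB_LG 2 and EMB_EG 4 (mean 0.48). Of 13 named calls ERL2 and BGLU18 held in every rerun. The 31 calls became 233 with array weights and 16 with only these groups fitted. Without EMB_EG 1, 2 or 3 there were 12, 17 or 19, and without EMB_LG 1 or 4 there were 14 or 13.

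Between 81 h and 100 h in vascular nuclei (4 arrays each), 166 genes were higher and 139 lower at 100 h. LOG4 rose by 2.52 (SE 0.558, adjusted p = 0.0184), from 1.85 ± 0.504 to 4.37 ± 1.26 (SD, n = 4), the single call of 21 vascular genes, also when adjusted over the list alone (list mean 0.34, camera adjusted p = 0.113). HSP70 rose by 3.29 (SE 0.505, adjusted p = 0.00268) and PGA4 by 3.43. Beside PGA4, the 25 other pollen genes had a mean of 1.18 with 6 rising (camera adjusted p = 7.48e-13). The calcium-binding PBP1 (AT5G54490) fell by 3.08, the germin-like GER3 (AT5G20630) by 2.93, and the Rubisco gene RBCS2B (AT5G38420) by 2.69. Of 23 photosynthesis genes 2 fell, RBCS1A by 1.09 and PSAF with adjusted p = 0.0195, and 12 did when adjusted over the list alone (mean -0.83, camera adjusted p = 2.67e-09). The seed maturation list was higher with 0 of 17 called in either adjustment (mean 0.60, ABI3 1.18; camera adjusted p = 0.00135; adjusted p = 0.166 with an estimated correlation), a call that ended without VSC_LG 3 (mean 0.32). Of the 15 named calls 10 held in every rerun, HSP70, GER3 and RBCS2B among them but not LOG4. The 305 calls became 489 with quantile normalization, 774 with array weights, 102 with only these groups fitted and 19 without VSC_EG 2 and 3. Without VSC_EG 1, 2, 3 or 4 there were 597, 120, 104 and 510, and without VSC_LG 2, 3 or 4 there were 154, 176 and 143.

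The ground tissue markers SCR and JKD rose in ground tissue nuclei between 81 h (4 arrays) and 100 h (3). The rise of SCR was 2.41 (SE 0.451, adjusted p = 0.00269), from 3.12 ± 0.526 (SD, n = 4) to 5.53 ± 0.39 (n = 3), and JKD by 2.21 (adjusted p = 0.00287); 2 of 8 ground tissue genes rose and 4 did when adjusted over the list alone (mean 0.80, camera adjusted p = 0.00138). FIL rose by 3.79 (SE 0.434, adjusted p = 9.97e-06), LAC2 by 3.73, ABCG15 by 3.54, ERL2 by 3.27 and VIM1 by 3.18. The cold-induced KIN2 (AT5G15970) fell by 3.36, the jacalin lectin JAL23 (AT2G39330) by 3.32, GER3 by 3.11 and HSP17.6II by 3.08. In all 261 genes were higher and 147 lower.

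Lists of the cell cycle and of the shoot apex and cotyledon were higher at 100 h. G2 and M phase had a mean of 1.03 (camera adjusted p = 3.7e-08), with KN rising by 2.84 as the single call of 19 and 8 rising when adjusted over the list alone. S phase had a mean of 0.99 (camera adjusted p = 8.92e-09), with MCM2 (AT1G44900) rising by 1.56 as the single call of 17 and 10 when adjusted over the list alone. Of 15 shoot apex and cotyledon genes 2 rose, FIL and the growth regulator ANT by 2.37, and 4 when adjusted over the list alone (mean 0.75, camera adjusted p = 5.31e-05). The photosynthesis list fell (mean -1.08, camera adjusted p = 6.61e-13), LHCB2.2 by 1.77 and PSBO2 by 2.21 as 2 of 23, and 16 when adjusted over the list alone. Lists that were lost with an estimated correlation were DNA methylation and Polycomb (mean 0.76, 3 of 23 rising, VIM1, AGO4 and AGO6 [AT2G32940], 9 when adjusted over the list alone), protoderm (0.76, 3 of 11, PDF1 by 2.05, 5 when adjusted over the list alone), vascular (0.60, 0 of 21, 3 when adjusted over the list alone) and auxin transport and synthesis (0.46, LAX1 [AT5G01240] by 1.25 as 1 of 15, 5 when adjusted over the list alone). Their camera adjusted p were 1.6e-07, 0.00135, 0.00356 and 0.0105, and with an estimated correlation adjusted p = 0.0768, 0.127, 0.107 and 0.116; the auxin call was also lost without dim genes or GSC_EG 4 (adjusted p = 0.0705). Without GSC_LG 2 the DNA methylation and Polycomb mean was 0.50 and the vascular call ended (adjusted p = 0.0734). The stress response list was lower with 0 of 12 called in either adjustment (mean -1.01, JAZ1 -1.25; camera adjusted p = 5.23e-05; adjusted p = 0.0728 with an estimated correlation), as was the seed coat list (mean -0.69, STK [AT4G09960] -1.64, TT4 -0.89, 0 of 16 called, 4 when adjusted over the list alone; camera adjusted p = 0.000263; adjusted p = 0.28 with an estimated correlation). Of the 25 named calls 12 held in every rerun, FIL, SCR, ANT, KN and VIM1 among them. The 408 calls became 235 with quantile normalization, 852 with array weights and 229 with only these groups fitted. Without GSC_EG 1 or 2 there were 261 or 247, and without GSC_LG 2 or 3 there were 127 or 239.

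In suspensor nuclei 13 genes were higher and 87 lower at 100 h than at 81 h (3 arrays each). RBCS1B fell by 5.24 (SE 0.608, adjusted p = 6.65e-06), from 8.07 ± 0.34 to 2.83 ± 1.54 (SD, n = 3), the germin-like GER3 and GER1 (AT1G72610) by 3.90 and 3.72, HSP70 by 3.89 and JAL23 by 3.32. BGLU29 (AT2G44470) rose by 2.56 (SE 0.509, adjusted p = 0.0117) and SDG29 (AT5G53430), a histone methyltransferase, by 1.96. Among the 23 photosynthesis genes 13 fell, LHCB2.2 by 2.86 and PSAF by 2.35, and 18 did when adjusted over the list alone (mean -1.79, camera adjusted p = 6.01e-36). Of 12 stress response genes 2 fell, HSP70 and HSFA2 by 2.53, and 4 when adjusted over the list alone. The mean was -0.72, the median -0.08 (camera adjusted p = 0.0182, or 0.296 with an estimated correlation). The call was also lost with quantile normalization and without SUS_EG 2 or SUS_LG 1 (adjusted p = 0.159 and 0.112). No suspensor gene passed in either adjustment, with ARF13 (AT1G34170) at -0.66 and a list mean of -0.003. The endosperm list was higher with 0 of 13 called and 1 when adjusted over the list alone (mean 0.32, HDG3 [AT2G32370] 1.12; camera adjusted p = 0.0358; adjusted p = 0.26 with an estimated correlation), a call lost with quantile normalization, with the array spread as a covariate (adjusted p = 0.0543), and without SUS_LG 2 (mean 0.14), SUS_EG 1 or SUS_EG 2 (adjusted p = 0.0708 and 0.11). The 100 calls became 33 with only these groups fitted. Without SUS_EG 2 or 3 there were 44 or 37, and without SUS_LG 1 or 3 there were 48 or 52.

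**Figure D3:**
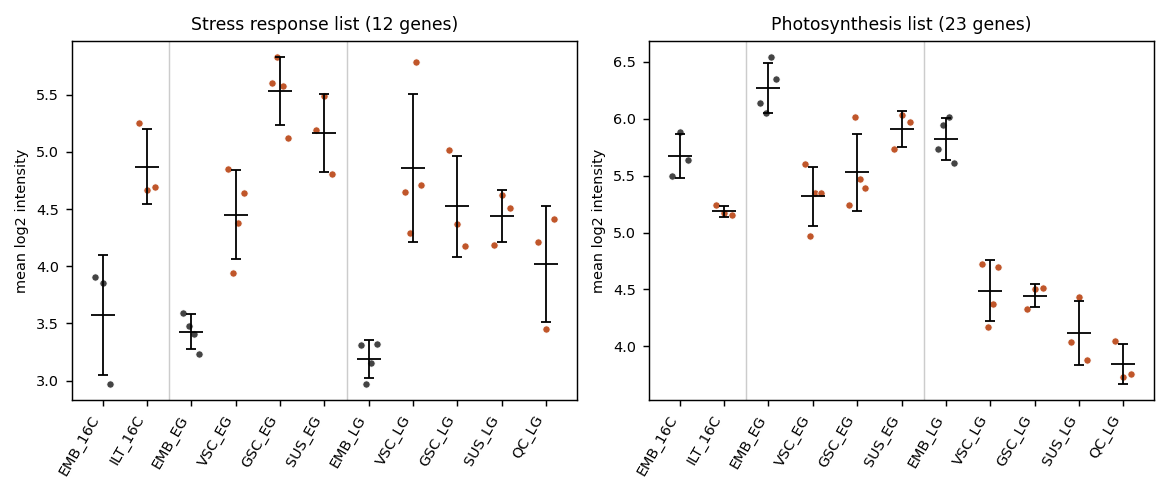
Mean log2 intensity of the stress response list (left) and the photosynthesis list (right) on each array, by group (points: arrays, whole embryo in grey; bars: mean ± SD; lines separate the stages). All 27 arrays of single cell types lay above the whole-embryo arrays of their stage for stress genes and below them for photosynthesis genes.

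Whether a cell type differed from the whole embryo by a different amount at 81 h and 100 h was tested as a difference of differences. In limma, 0 genes passed for vascular nuclei (2166 at an unadjusted p under 0.05) and 0 for ground tissue nuclei (1823). For suspensor nuclei 2 genes passed. RBCS1B stood at 0.22 against the whole embryo at 81 h and at -4.86 at 100 h, a difference of -5.08 (SE 0.805, adjusted p = 0.00979), and HSP70 at 4.03 and -0.31, a difference of -4.34 (SE 0.772, adjusted p = 0.0376). Without VSC_EG 1 or 4 or EMB_EG 4 the vascular count was 3, 7 or 2, and without GSC_EG 3, EMB_EG 1, EMB_EG 4 or GSC_LG 1 the ground tissue count was 1. Without SUS_EG 1, 2 or 3 the suspensor count was 7, 5 or 1, without SUS_LG 1, 2 or 3 it was 0, 1 or 1, and without EMB_EG 4 or EMB_LG 1 it was 1.

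Genes called the same way against the whole embryo at both stages, with different whole-embryo arrays, numbered 57 for vascular nuclei (14 higher, 43 lower), where independent lists would share 2.34. For ground tissue nuclei 29 were shared (18 higher, 11 lower, 0.772 by chance). For suspensor nuclei the 4 shared genes, all lower, were AT3G05730, AT3G07270, EXT4 and NIA2 (0.274 by chance). No gene was called in opposite directions at both stages in any of the 3 cell types. Without VSC_EG 3, EMB_EG 1 or 3, VSC_LG 2 or 3, EMB_LG 1, 3 or 4 the vascular count was 32, 34, 32, 29, 22, 36, 25 or 34. Without GSC_LG 1, 2, 3 or EMB_LG 1, 2, 3 the ground tissue count was 7, 11, 15, 19, 18 or 14. The suspensor count was 1 without SUS_EG 3, EMB_EG 1, SUS_LG 2 or 3 and 2 without EMB_EG 3, EMB_LG 2 or 3.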

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

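Tests chosen only after the result was seen were those of the identity of the cell types, of ribosomal genes in GSC_LG, of the lists on stage differences, of lists without single arrays and of the added lists of pollen, rapid wound and touch response, cytosolic ribosome and plastid-encoded genes, with the permutation test and the array spread as a covariate.

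In groups of 4 arrays, 292 sets of values were searched for an array set apart from the rest, and 15 were found against 14.6 by chance, which gives about 1 in 20. Among list means these were 6 of 85. The root meristem list stood at 2.19 in VSC_EG 4 (others 2.41 to 2.43), the G2 and M phase list at 3.05 in GSC_EG 3 (2.35 to 2.44) and the auxin response list at 3.11 in GSC_EG 4 (3.25 to 3.27). The seed maturation list stood at 3.13 in EMB_EG 4 (2.30 to 2.41), the shoot apex and cotyledon list at 2.83 in VSC_LG 4 (2.60 to 2.63) and the seed coat list at 5.74 in VSC_LG 1 (4.80 to 4.90). Among named genes they were 9 of 202. In the sorted cells FBS3 stood at 4.37 in VSC_EG 2 (others 6.12 to 6.35), RBCS2B at 7.75 in VSC_EG 1 (6.97 to 7.06) and JAL23 at 4.54 in GSC_EG 4 (5.49 to 5.60). In EMB_EG, BXL1 stood at 4.64 in array 2 (5.17 to 5.27), and in array 4 PAN at 3.03 (2.14 to 2.27) and EMS1 at 4.27 (4.98 to 5.11). In EMB_LG, EXT4 stood at 5.05 in array 4 (6.56 to 6.63), PUM12 at 1.91 in array 2 (3.20 to 3.27) and RALFL8 at 6.79 in array 1 (4.05 to 4.45).

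Between 81 h and 100 h the difference from the whole embryo changed for RBCS1B (-5.08) and HSP70 (-4.34) in suspensor nuclei by limma. Of 51 list tests on these stage differences 5 passed by camera and 1 with an estimated correlation. The photosynthesis list in suspensor nuclei had a mean difference of -1.34 (camera adjusted p = 5.13e-14; adjusted p = 0.00138 with an estimated correlation). The seed coat list in suspensor nuclei had 0.88 (camera adjusted p = 3.3e-05; adjusted p = 0.507 with an estimated correlation). In ground tissue nuclei the photosynthesis list had -0.64, the stress response list -0.77 and the DNA methylation and Polycomb list 0.43 (camera adjusted p = 0.00255, 0.0187 and 0.0143; adjusted p = 0.507, 0.507 and 0.57 with an estimated correlation).

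Stress response genes were higher in nuclei of single cell types than in whole-embryo nuclei, by a mean of 1.40 over arrays within stage (permutation p = 1e-05, the smallest 100000 resamples can give). All 27 arrays lay above the whole-embryo arrays of their stage. Unequal array distributions are argued against as the cause. After quantile normalization the shift kept its larger part (0.864 or more) in 8 of 8 comparisons. RMA's own effect was not tested. Stress of the nuclei during sorting is a candidate explanation: 18 other rapid wound and touch genes rose as a set by camera in 8 of 8 comparisons (means 0.342 to 1.02), though with an estimated correlation adjusted p = 0.0685 in VSC_EG, 0.168 in SUS_EG and 0.0764 in QC_LG, and 1 isolation protocol is given for all groups. That set was no longer called in SUS_EG without SUS_EG 1 or 2 or EMB_EG 2 or 4 (adjusted p = 0.0884 to 0.171) nor in QC_LG without QC_LG 3 (0.0588), and its mean in GSC_LG fell from 0.68 to 0.35 with the array spread as a covariate. Cell type identity stays open too (shifts from 0.835 to 2.11).

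Genes known from pollen were higher in SUS_EG, VSC_LG and QC_LG than in the whole embryo; in SUS_LG 25 other pollen genes stood at 0.376 (adjusted p = 0.485 with an estimated correlation; 0.22 and not called without SUS_LG 1), VGD1 at 6.74 and AGP6 at 5.83. A difference in the spread of values between arrays is argued against, since the 25 other pollen genes kept a mean shift of at least 0.724 with that spread as a covariate. Nuclei or RNA of pollen are a candidate explanation, as a hypothesis: the 25 other pollen genes, none of which any of the 17 lists holds, had shifts of 0.721 (SUS_EG), 0.873 (VSC_LG) and 1.27 (QC_LG, 0.76 without QC_LG 3), with adjusted p = 0.117, 0.0469 and 0.0249 with an estimated correlation. Their most abundant genes lay high, VGD1 at 6.46, 7.92 and 8.27 and AGP6 at 5.86, 6.60 and 7.59 in these groups, against VGD1 at 4.23 and 5.70 and AGP6 at 3.32 and 4.64 in EMB_EG and EMB_LG. The INTACT capture should remove nuclei without the tag, how many of these genes embryos also express was not tested, and no biological explanation was tested.

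Photosynthesis genes were lower in nuclei of single cell types, with a mean shift of -0.925 (permutation p = 1e-05, with the same limit). All 27 arrays lay below the whole-embryo arrays of their stage. Unequal array distributions are argued against, since 8 of 8 comparisons kept the larger part of the shift after quantile normalization (smallest -0.327). RMA's own effect was again not tested. Plastids carried over into whole-embryo preparations could not be judged here. The named photosynthesis genes are nuclear, so RNA made in plastids would not by itself hold them, and plastid-encoded genes do not test them. The latter had a mean shift above -0.25 in 3 of 8 comparisons (VSC_EG 0.185, GSC_EG 0.0355, SUS_EG -0.0516) and down to -1.82 in QC_LG. The VSC_EG value was -0.05 without VSC_EG 2 or 3 and -0.53 without both. Cytoplasmic RNA carried over stays open: 19 cytosolic ribosome genes were lower, as it predicts, in ILT_16C (-0.62), VSC_EG (-0.722), VSC_LG (-0.755), SUS_LG (-0.735) and QC_LG (-0.722, or -0.36 without QC_LG 2). Of these VSC_LG passed with an estimated correlation (adjusted p = 0.0451). The shift was above -0.25 in 3 of 8 comparisons (GSC_EG 0.009, SUS_EG -0.21, GSC_LG 0.328). The GSC_LG value of 0.328 (SE 0.256) became 0.105 with quantile normalization, 0.0244 with the array spread as a covariate and 0.08 without EMB_LG 2, so that explanation stays open there too. Lower expression in the cell types themselves was not tested and stays open.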

How the results depend on the processing

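Beside the later tests named above, leaving out VSC_EG 2 and 3 together was chosen after seeing the data. The other alternatives were planned. No named call changed sign in a rerun. Of 240 named calls 80 held in every rerun, leaving out single arrays included, and of 305 named values not called 244 were called in none. Median centring left all counts but 1 within 1.5 times the reported count, and the intensity trend and the added 2-fold threshold left all of them there. In simulated data 2-fold changes were mostly missed, so signal and array number limit small changes, and dim genes lie near background. The cause of each move below was not tested, except where fewer arrays or fewer genes entered the fit.

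With array weights the counts became 37 for ILT_16C against EMB_16C (125 as reported), 2010 for VSC_EG (599), 973 for GSC_EG (313), 156 for SUS_EG (55), 386 for VSC_LG (219) and 306 for GSC_LG (125) against the whole embryo. They became 1019 for VSC_EG against GSC_EG (206), 895 for VSC_LG against GSC_LG (344), 184 for EMB_EG against EMB_16C (52), 233 for EMB_LG against EMB_EG (31), 774 for VSC_LG against VSC_EG (305) and 852 for GSC_LG against GSC_EG (408). The stage differences became 16 (vascular, 0), 31 (ground tissue, 0) and 5 (suspensor, 2) in limma, and the genes called at both stages 123 (57), 89 (29) and 8 (4).

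With only the groups compared in the fit, fewer arrays estimate the spread. The counts were 14 for ILT_16C, 279 for VSC_EG, 156 for SUS_LG (269) and 43 for QC_LG (417) against the whole embryo, 5 for VSC_EG against GSC_EG, 7 for EMB_EG against EMB_16C, 16 for EMB_LG against EMB_EG, 102, 229 and 33 for the stages of vascular, ground tissue and suspensor nuclei (305, 408 and 100), 1, 3 and 1 for their stage differences and 69 and 10 for ground tissue and suspensor genes at both stages.

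With quantile normalization the counts were 195 for GSC_EG, 338 for VSC_LG, 79 for GSC_LG and 664 for QC_LG against the whole embryo, 45 for VSC_EG against GSC_EG, 144 for VSC_LG against GSC_LG, 489 for VSC_LG against VSC_EG, 235 for GSC_LG against GSC_EG and 2 for the vascular stage difference. Higher and lower calls were then 41 and 38 for GSC_LG against EMB_LG (88 and 37 as reported), 60 and 84 for VSC_LG against GSC_LG (90 and 254) and 20 and 14 for EMB_LG against EMB_EG (13 and 18). They were 1 and 2 for the suspensor stage difference (0 and 2), and at both stages 34 and 47 for vascular (14 and 43), 10 and 12 for ground tissue (18 and 11) and 1 and 4 for suspensor nuclei (0 and 4). Centring gave 122 and 97 for VSC_EG against GSC_EG (144 and 62), 69 and 416 for VSC_LG against GSC_LG, 5 and 43 for vascular nuclei at both stages, and 1 for the suspensor stage difference. The median of all genes in VSC_LG against GSC_LG was 0.023 with quantile normalization.

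Without dim genes, which lowers the number of genes tested, there were 110 for VSC_EG against GSC_EG and 79 for EMB_EG against EMB_16C. With the array spread as a covariate there were 193 for ILT_16C, 141 for GSC_EG and 13 for GSC_LG against the whole embryo, 68 for VSC_EG against GSC_EG, 17 for VSC_LG against GSC_LG, 93 for EMB_EG against EMB_16C, 1 for the ground tissue stage difference and 5 for ground tissue genes at both stages. Without VSC_EG 2 and 3 there were 96 for VSC_EG against EMB_EG, 6 for VSC_EG against GSC_EG, 19 for VSC_LG against VSC_EG and 18 for vascular genes at both stages.

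The replicate numbers did not pair the arrays: the correlation of deviations of same-numbered arrays ran from -0.114 to 0.208 over the 15 comparisons, and in no comparison was it above 0.1 for every pair. The replicate block changed the vascular stage difference from 0 to 1, ended 1 list call (S phase, QC_LG) and moved no other count by over 1.5 times.

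Leaving out 1 array at a time gave 51 to 99 genes for ILT_16C, 210 to 985 for VSC_EG, 144 to 241 for GSC_EG, 6 to 67 for SUS_EG, 77 to 186 for VSC_LG, 36 to 158 for GSC_LG, 54 to 232 for SUS_LG and 149 to 624 for QC_LG against the whole embryo. It gave 10 to 720 for VSC_EG against GSC_EG, 25 to 406 for VSC_LG against GSC_LG, 18 to 76 for EMB_EG against EMB_16C, 12 to 43 for EMB_LG against EMB_EG, 104 to 597 for VSC_LG against VSC_EG, 127 to 414 for GSC_LG against GSC_EG and 37 to 101 for SUS_LG against SUS_EG. The stage differences ran from 0 to 7 (vascular), 0 to 1 (ground tissue) and 0 to 7 (suspensor), and the counts at both stages from 22 to 63, 7 to 33 and 1 to 4.

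Of 255 list tests 77 passed by camera (33 higher, 44 lower) and 21 with an estimated correlation (12 higher, 9 lower). The latter gave the highest adjusted p of the 6 alternatives in 77 of 77 passing tests, and 21 held in all 6. Estimating the correlation ended 56 calls, fry 29, quantile normalization 7, the filter on dim genes 6 and array weights 6, and 0 changed sign. Leaving out 1 array at a time ended 29 of the 77 calls and 8 of 50 of the added lists, and turned 1 list mean, that of seed coat in ILT_16C.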

Other observations

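The added lists were chosen after the named genes were seen. Genes of the secondary cell wall were higher in both inner tissues at 100 h. In vascular nuclei 5 of 18 rose against the whole embryo, FLA12 (AT5G60490) by 2.68 and the cellulose synthase IRX3 (AT5G17420) by 2.02, with a list mean of 0.95 (camera adjusted p = 2.29e-09; adjusted p = 0.00296 with an estimated correlation). In ground tissue nuclei 4 rose, FLA12 by 2.54 and the xylan synthesis gene IRX9 (AT2G37090) by 2.40 (mean 0.85, camera adjusted p = 2.67e-05; adjusted p = 0.0249 with an estimated correlation). Between 81 h and 100 h the list mean rose by 0.96 in vascular and 0.78 in ground tissue nuclei, with IRX3 rising by 2.65 and 2.43, while in the whole embryo it stood at 0.09 (camera adjusted p = 0.727).

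Lists of organelle-encoded genes were lower than in the whole embryo in 4 groups. The 92 mitochondrion-encoded genes had a mean of -0.91 in ILT_16C (camera adjusted p = 2.46e-13; adjusted p = 0.0429 with an estimated correlation) and of -0.89 in QC_LG, with 11 falling (2.56e-14; adjusted p = 0.0402 with an estimated correlation; mean -0.55 without QC_LG 2). The mean was -0.41 in VSC_LG (0.000145; adjusted p = 0.32 with an estimated correlation; -0.26 without EMB_LG 4), -0.74 in SUS_LG (camera adjusted p = 1.5e-09; adjusted p = 0.0829 with an estimated correlation) and 0.69 in GSC_LG (1.5e-09; adjusted p = 0.0829 with an estimated correlation), where the array spread as a covariate gave 0.26 and ended the call (adjusted p = 0.0777). The 14 plastid-encoded genes had means of -1.27 in ILT_16C, -1.07 in VSC_LG, -1.16 in SUS_LG and -1.82 in QC_LG, with 1, 1, 2 and 5 falling (adjusted p = 0.0413, 0.0451, 0.0413 and 0.00502 with an estimated correlation). The QC_LG arrays split, with QC_LG 1 at 7.91 and the others at 5.42 and 5.63, against 7.94 to 8.45 in EMB_LG. The list stood at -0.25 in GSC_LG (-0.64 with that covariate and -0.15 without EMB_LG 4). In vascular against ground tissue nuclei at 100 h, mitochondrion-encoded genes had a mean of -1.11 (-0.63 with that covariate) and the 19 cytosolic ribosome genes of -1.08, each with adjusted p = 0.0249 with an estimated correlation. From 81 h to 100 h plastid-encoded genes were lower in vascular (mean -1.26, adjusted p = 0.0296 with an estimated correlation; -0.55 without VSC_EG 2 and 3) and suspensor nuclei (-1.11, 0.0249). Rapid wound and touch genes were lower at 100 h in ground tissue nuclei (mean -0.92, adjusted p = 0.00726 with an estimated correlation) and in the whole embryo (-0.60, 0.0249). In all 50 of the 90 tests of added lists passed by camera.

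Of the 17 lists, 3 passed in no comparison. The suspensor list ran from -0.45 (ILT_16C against EMB_16C, camera adjusted p = 0.0928) to 0.43 (GSC_LG against GSC_EG, 0.123). The auxin response list ran from -0.16 (VSC_LG against GSC_LG, 0.17) to 0.10 (GSC_LG against EMB_LG, 0.356). Within it ARF3 (AT2G33860), an auxin response factor of organ polarity, was called in 4 comparisons and rose by 2.65 between 81 h and 100 h in ground tissue nuclei (adjusted p = 3.8e-05). The cytokinin list ran from -0.19 (QC_LG against EMB_LG, 0.38) to 0.19 (VSC_LG against GSC_LG, 0.425); LOG4 is held by this list and by the vascular list. ARF3 was chosen after its values were seen.

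Other same-sized splits of the same arrays were refitted with limma. In 12 comparisons the real split alone of 35 called as many genes, a share under 0.05 not adjusted over the 15 comparisons. The real count and the highest other were 599 and 156 for VSC_EG, 313 and 6 for GSC_EG, 55 and 20 for SUS_EG, 219 and 2 for VSC_LG, 125 and 34 for GSC_LG, 269 and 27 for SUS_LG and 417 and 70 for QC_LG, each against the whole embryo. They were 206 and 85 for VSC_EG against GSC_EG, 344 and 70 for VSC_LG against GSC_LG, 31 and 4 for EMB_LG against EMB_EG, 305 and 15 for VSC_LG against VSC_EG and 408 and 168 for GSC_LG against GSC_EG. For EMB_EG against EMB_16C 2 of 35 splits gave as many genes as the real 52 (highest other 59), so chance is not excluded. Without 1 array some counts fell under that highest other: 16 or 6 for SUS_EG without SUS_EG 2 or 3, 10, 38, 43 or 48 for VSC_EG against GSC_EG without VSC_EG 2, VSC_EG 3, GSC_EG 1 or GSC_EG 3, and 25 and 127 for VSC_LG and GSC_EG against GSC_LG without GSC_LG 2; the splits were not refitted with fewer arrays. The splits of ILT_16C with EMB_16C (125, highest other 6) and of SUS_LG with SUS_EG (100, highest other 0) number 10 each, too few for a share under 0.05.

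For the stage differences of vascular and ground tissue nuclei limma called 0 genes. All 100 splits reach a count of 0 whatever the data, so they test nothing here. The highest called 6 and 5 genes at the adjusted threshold. In suspensor nuclei 10 of 100 splits gave at least the real 2, so chance is not excluded, and the highest other split called 208, which points to a structure of the samples that was not tested. Of genes called the same way at both stages, the real split of 100 gave 57 in vascular nuclei (highest other 0). In ground tissue nuclei it gave 29 (0). Other splits called fewer genes in each stage and so had fewer to share, so agreement between stages was not tested. In suspensor nuclei the real split alone gave 4 (highest other 2), but the count was 1 or 2 without single arrays and rests on them.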
